A study of Mus musculus with 2 samples.

How the data were processed

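DNase-seq maps open chromatin by cutting nuclei with DNase I and sequencing the ends that the enzyme leaves. The samples were 2 libraries of whole thymus from female mice 4 days old, of the hybrid strain B6CASTF1/J, a cross of C57BL/6J with CAST/EiJ. Both belong to 1 group, so no test between conditions was possible. They are called replicate 1 and replicate 2 after the replicate numbers in the labels, which name a separate animal for each. The labels give both animals the same donor identifier, so p-values over genes or footprints describe these libraries and not the spread of mice.

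Per the labels and per the file headers, the files use the mm10 build and each was made from the filtered alignments of 1 library. The aligner, the peak and footprint callers, their versions and the thresholds were not given in the sources used here. The authors deposited 2 peak lists per library with a signal value per peak, called peak strength here. Strengths were whole multiples of 1 step per library within a tolerance of 0.05 steps, for 99.999% of peaks in replicate 1 and 100% in replicate 2. The scaling is not stated, and the sequencing depth is unknown. The authors also deposited p-values as a false discovery rate (FDR) of the cut rate along the genome, all under 0.05. The score that the authors deposited with each footprint was 0.01 throughout and ranked nothing.

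The longer peak list of each library served as the main list and the shorter as the stricter alternative. Every peak of the longer lists touched bases under an FDR of 0.05, and every peak of the shorter lists touched bases under 0.001. Those thresholds were a test on the files and are not stated by the authors. Peak summits were not usable, so centres stood for peaks. Reads of the CAST/EiJ chromosome were aligned to a C57BL/6J sequence, and alleles were not analysed here.

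Peaks were shared if they overlapped by at least 1 base, and chance sharing came from 100 circular shifts within chromosomes. Promoter peaks had their centre within 1000 bases of a transcription start site (TSS) of GENCODE M21. Distal peaks lay farther from every TSS, inside a gene or within 25000 bases of it. The background was 21911 protein-coding genes. Promoter peaks of gene lists were tested with a two-sided Fisher's exact test per library. Distal peaks were tested by a two-sided permutation test, setting a list's median against 10000 random lists matched on region length in bins of 200 genes. Peaks of the 2 libraries were paired by largest overlap for strength ratios. Motif matches on either strand in footprints extended by 3 bases were compared, by Fisher's exact test, with windows of the same width in the same peaks outside all footprints. Each family of tests was adjusted by Benjamini-Hochberg, and a list or motif was called only at an adjusted p below 0.05 with the same direction in both libraries. Genes, peaks and footprints are not independent replicates.

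The 16 gene lists held 218 genes, all found in the annotation: T lineage transcription factors (18), T cell receptor signalling and coreceptors (22), receptor gene recombination (8), effector, regulatory and NK cells (15), thymic epithelium (15), B cells (12), myeloid cells (14), dendritic cells (11), erythroid cells (12), mesenchyme (12), endothelium (12), liver (12), neurons (12), skeletal muscle (12), cell cycle (16) and housekeeping (15). The genes named were drawn from 30 fixed genes, the 10 protein-coding genes with most peaks, the genes at the 5 strongest shared peaks, and list members lacking a promoter peak in both libraries where 4 or fewer. The lists, the 18 motifs, the naming rule, the tests and most alternatives were chosen before the data were examined. Gene families, receptor segments and the regions around them, GC-matched windows, reordered letters of AP-1 and GATA set against windows, and merged distal peaks were chosen afterwards.

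Alternatives were the stricter list, other overlap rules, equal peak numbers, other TSS distances and sets, other distal regions, and each library alone. The scripts were tested on simulated data. For promoter peaks, 93.9% of lists set wholly open were called and 0% of unchanged lists, over 21911 genes and 100 simulations. Unchanged genes were drawn separately for each library there, whereas the real libraries shared most promoter peaks. That 0% is therefore not a rate of false calls for these data. For distal peaks, 83.8% of lists raised 4-fold, 20% of lists raised 2-fold and 0% of unchanged lists were called (20 simulations), so a list without a call was not shown to equal other genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.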

Results

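Accessible chromatin of the newborn mouse thymus was mapped by DNase-seq in 2 libraries. Replicate 1 held 116560 peaks and replicate 2 held 142851, a mean of 129706 ± 18591 (SD, n = 2). The median peak was 180 bases wide in both. Peaks covered 0.903% of the sequenced genome in replicate 1 and 1.06% in replicate 2. Median peak strength was 0.647 and 0.649, in the units of the deposited signal. The authors' lists were called per library, so a missing peak means that none was called and not that the site was closed.

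The libraries shared most of their strong peaks. Of the peaks of replicate 1, 80.3% overlapped a peak of replicate 2, and 65.6% the other way, a mean of 73.0%. Circular shifts gave 2.04% on average and at most 2.23% in 100 draws. The 2 observed shares rest on the same overlaps set against lists of unlike length, so their difference is no spread between libraries. With equal numbers of the strongest peaks they were 76.5% and 76.4%. Sharing rose with strength, from 31.8% in the weakest 10% of replicate 1 to 99.9% in its strongest 10%, and from 9.06% to 99.5% in replicate 2. Over 90090 paired peaks, Spearman's rho of strength was 0.947 and Pearson's r on the log2 scale was 0.959. These are correlations across peaks, which are not independent replicates. Paired peaks were stronger in replicate 2 by a median of 0.52 on the log2 scale, or 1.44-fold.

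**Figure D1:**
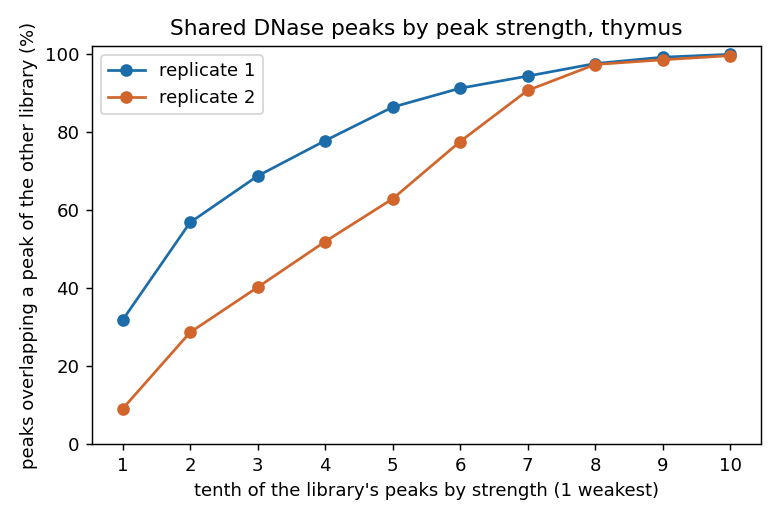
Share of peaks that overlapped a peak of the other library (y axis, percent) by rank of peak strength in 10 equal bins (x axis, 1 the weakest), 1 line per library. The line of replicate 1 runs from 31.8% to 99.9% and that of replicate 2 from 9.06% to 99.5%.

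The strongest shared peaks did not lie at genes of the T lineage. The first, on chromosome X at 143482981 to 143483140, was intergenic, 35530 bases from a TSS of Pak3, with strengths of 110 and 52.4. The second, at 169998261 to 169998420 of the same chromosome, lay in an intron of Mid1 (48.9 and 81.2). Another lay in an exon of Lars2, a mitochondrial leucyl-tRNA synthetase gene, on chromosome 9 at 123461921 to 123462080 (42.9 and 78.2). The fourth lay in an exon of CT010467.1 on chromosome 17 at 39846781 to 39846900, 117 bases from a TSS of Gm42418 (46.7 and 63.3), and the last on chromosome 1 at 195241541 to 195241800, 664 bases from Gm27940 (30.1 and 56.5). In 3 of the 5, over 50% of the 32-base words of the sequence also occurred elsewhere in the genome, against 2.5% of 200 random peaks, so reads there can come from other copies.

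Promoters were the most enriched position. Peaks within 1000 bases of a TSS made up 33.1% ± 2.00 of all peaks (SD, n = 2), against 6.34% for shifted peaks (highest draw 6.67%). Introns held 32.9% ± 0.892 against 40.2% by chance, exons 5.36% ± 0.639 against 3.39%, and intergenic sequence 28.7% ± 0.472 against 50.1%. Promoter peaks of replicate 1 were shared more often than other peaks, at 85.1% against 77.8%, and those of replicate 2 at 75.3% against 61.1%. They were also stronger, with median strengths of 0.889 against 0.563 and of 1.11 against 0.557. Strength was not held equal in this comparison.

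All 18 T lineage transcription factors, among them Tcf7, Bcl11b, Gata3, Runx3 and Notch1, had a promoter peak in both libraries. So did all 22 genes of T cell receptor signalling and coreceptors, including Cd3e, a chain of the receptor complex, the coreceptors Cd4 and Cd8a, and the kinase gene Lck. The background was 66.8% of other protein-coding genes in replicate 1 and 69.6% in replicate 2. Cell cycle genes (16 of 16) and housekeeping genes (15 of 15) were likewise open at every promoter, so full promoter access was not particular to T cell genes. Liver genes stood at the other end, with a promoter peak at 1 of 12, and Alb, which encodes serum albumin, had none. Adjusted p by Fisher's exact test was 0.00806 and 0.0164 for the T lineage factors in replicates 1 and 2, 0.00135 and 0.00504 for T cell receptor signalling, 0.00931 and 0.0191 for the cell cycle, 0.0109 and 0.0269 for housekeeping, and 0.000716 and 0.000281 for liver.

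The other lists did not pass in both libraries. Receptor gene recombination had 8 of 8 promoters with a peak in each library, Rag1, Rag2 and Dntt included (adjusted p = 0.135 and 0.279 by the exact test). The effector, regulatory and NK cell list had 9 of 15 in each, with Foxp3, the regulatory T cell factor, at a promoter strength of 5.34 ± 2.60 (SD, n = 2). Thymic epithelium had 8 and 9 of 15. Aire had a promoter peak in both, whereas Foxn1 and Psmb11 had none. B cell genes had 6 and 7 of 12, with a peak at Pax5 and none at Cd79a, and myeloid genes 7 and 7 of 14, with a peak at Spi1 and none at Csf1r. Dendritic cell genes had 7 and 6 of 11, and Xcr1, Clec9a, Siglech and Ciita had no promoter peak in either library. Erythroid genes had 5 and 6 of 12, Gata1 included. Mesenchyme had 6 and 7 of 12 (Col1a1 with a peak) and endothelium 7 and 7 of 12 (Pecam1 with a peak). Neuronal genes had 10 and 11 of 12, including Neurod1 at a strength of 0.323 ± 0.0645, and Stmn2 had none. Skeletal muscle had 3 and 6 of 12, and Myod1 had a promoter peak in replicate 2 alone. Muscle was below the background in both libraries and passed the exact test in replicate 1 (adjusted p = 0.0109) but not in replicate 2 (0.327).

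Distal peaks set the T cell genes apart. The T lineage transcription factors had a median of 18.5 distal peaks per gene in replicate 1 and 33 in replicate 2, against 4.5 and 5 in random lists. Tcf7, a factor of early T cell commitment, had 50 and 52, Bcl11b had 32 and 52, Notch1 29 and 39, and Runx3 11 and 31. Gata3 had few, 3 and 4, but 10 and 12 promoter peaks. T cell receptor signalling genes had medians of 13 and 16 against 3 and 3.5. Cd4 had 13 and 37, Cd8a 12 and 33, Cd3e 9 and 22, and Lck 13 and 14, whereas Ptcra, the pre-T cell receptor alpha chain, had 6 and 4 and Themis 5 and 6. Both lists passed with an adjusted permutation p of 0.0016 in each library, the smallest that 10000 draws and 16 lists gave here.

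**Figure D2:**
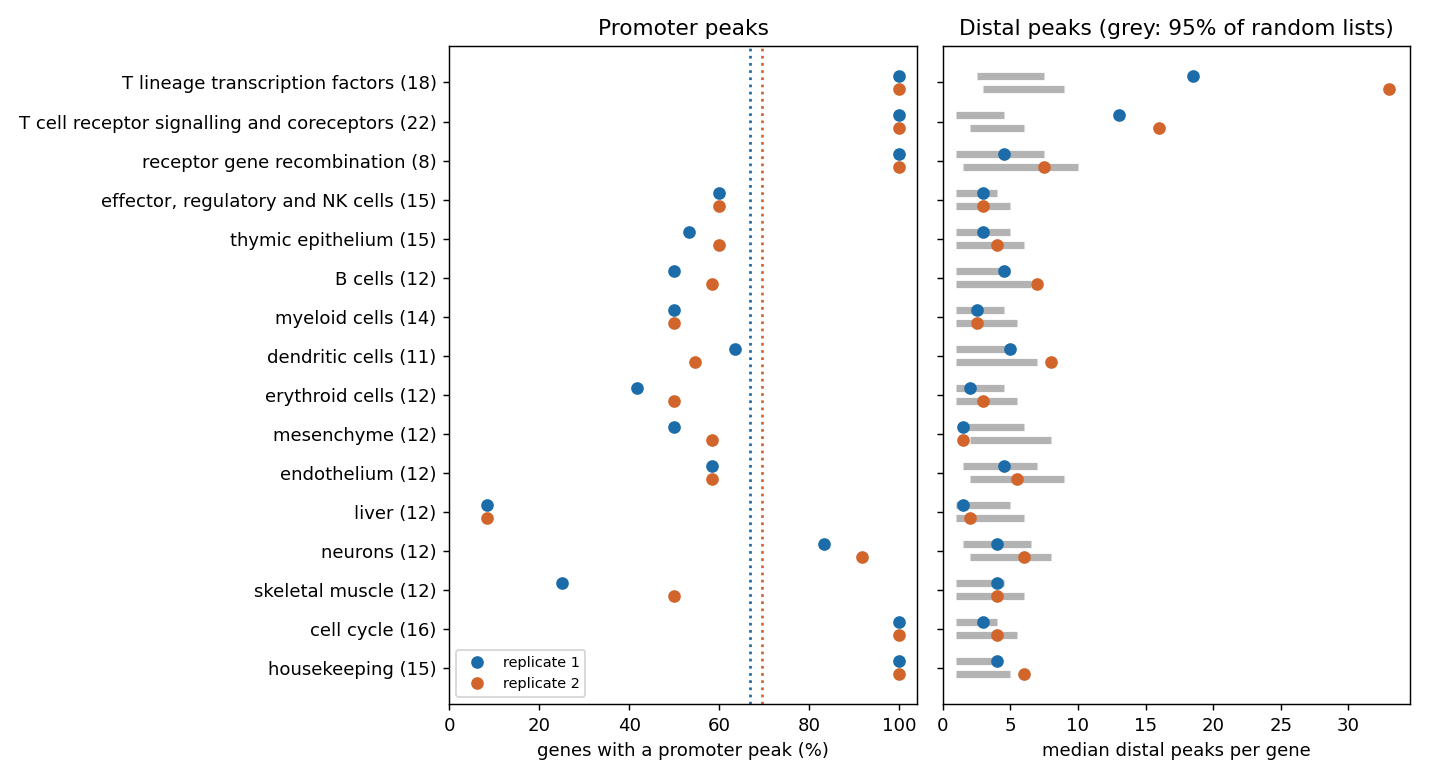
Left, percent of each list's genes with a promoter peak (points, 1 per library; dotted lines, other protein-coding genes); right, median distal peaks per gene (points) with the central 95% of random lists in grey. List sizes are in brackets; both T cell lists lie beyond the grey bars in each library, at medians of 18.5 and 33 and of 13 and 16.

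No other list passed for distal peaks. Medians in replicates 1 and 2 were 4.5 and 7.5 for receptor gene recombination, 3 and 3 for effector, regulatory and NK cells, 3 and 4 for thymic epithelium, 4.5 and 7 for B cells, 2.5 and 2.5 for myeloid cells, and 5 and 8 for dendritic cells. They were 2 and 3 for erythroid cells, 1.5 and 1.5 for mesenchyme, 4.5 and 5.5 for endothelium, 1.5 and 2 for liver, 4 and 6 for neurons, 4 and 4 for skeletal muscle, 3 and 4 for cell cycle and 4 and 6 for housekeeping. In replicate 2 alone, unadjusted permutation p was below 0.05 for more peaks at B cell (0.038), dendritic cell (0.023) and housekeeping genes (0.0178) and fewer at mesenchyme (0.0384). Random medians of these lists ranged from 2 to 3.5 in replicate 1 and from 3 to 4.5 in replicate 2. Among members, Dntt, which adds bases at receptor joints, had 33 and 39 distal peaks, Il2ra 19 and 24, Pecam1 12 and 27, Foxn1 7 and 9, Psmb11 7 and 7, Pax5 7 and 8, Spi1 6 and 9, and Alb 3 and 2.

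The recombinase genes Rag1 and Rag2 differed most between libraries among the fixed genes. Rag1 had 7 distal peaks in replicate 1 and 34 in replicate 2, and Rag2 had 8 and 47. Both lie on chromosome 2, Rag2 at 101624718 to 101632529 and Rag1 at 101638282 to 101649501. The joint region from 101599718 to 101674501 held 18 peaks of median strength 0.801 in replicate 1 and 64 of median strength 0.360 in replicate 2. With 1 library of each there is no test of this difference.

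**Figure D3:**
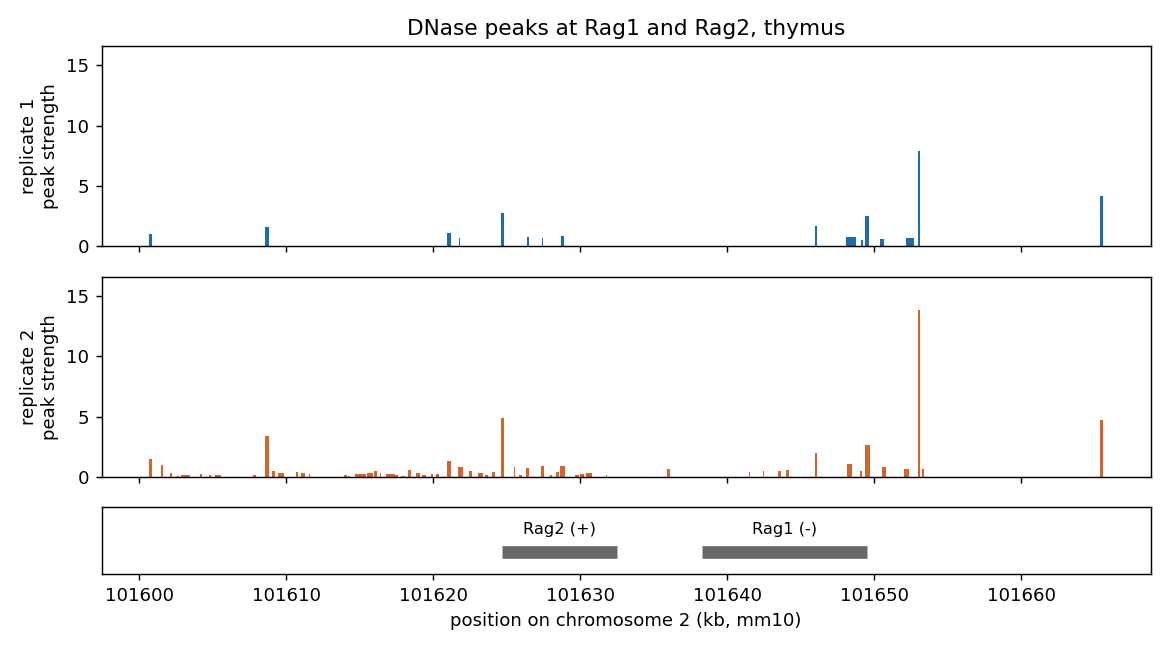
Peaks at Rag1 and Rag2 on chromosome 2 (x axis, kb in mm10), with peak strength in the units of the deposited signal (y axis) in replicate 1 (upper) and replicate 2 (middle), and the genes with their strands (lower). Replicate 2 has 64 peaks against 18, most of them weak.

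The genes with most peaks were mainly long ones. Gm20388, a gene model of 4434882 bases on chromosome 8, had 670 ± 127 (SD, n = 2), and Fgfr2 as annotated over 2960900 bases had 226.5 ± 16.3. Gse1 had 117.5, Ulk4 108.5, Cacna1d 106.5, Gm20696 99.5, Gm45062 86.5, Zfyve28 83.5, Foxp1 83 and Pde4d 80.5. Gse1 lies within Gm20388, and Gm20696 overlaps Foxp1, so peaks there were counted for both genes of each pair. Cacna1d, a calcium channel gene, had 61 peaks in replicate 1 and 152 in replicate 2.

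Peak strength was compared between libraries at the same lists, as a description of 2 libraries. At T lineage transcription factors the median log2 ratio of replicate 2 over replicate 1 was 0.81, against 0.66 in random lists of like strength (percentile 99.7). At dendritic cell genes it was 0.40 against 0.63 (percentile 1.05), and at T cell receptor signalling genes 0.57 against 0.66 (percentile 6.71). By permutation, 0 lists passed after adjustment and 2 had an unadjusted p below 0.05, the T lineage factors (0.0064, adjusted 0.102) and dendritic cells (0.0212, adjusted 0.17).

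Chromosome X carried fewer peaks for its length than the autosomes, at 21.4 ± 2.86 per megabase against 52.6 ± 7.56 (SD, n = 2). The ratio was 0.407 ± 0.00413. Chromosome 11 had 83.5 ± 12.1 per megabase. On chromosome Y 65 peaks were called in replicate 1 and 66 in replicate 2, although the animals are labelled female.

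Footprints are short protected stretches within accessible DNA. Replicate 1 had 348229 and replicate 2 had 440424, with median widths of 10 and 11 bases, and 83.4% and 76.7% lay inside a peak of the same library. Of all footprints, 61.2% and 45.9% overlapped a footprint of the other library, a mean of 53.6%. These 2 shares also rest on lists of unlike length, so their difference is no spread between libraries. Among footprints inside peaks the mean was 54.6%, against 40.4% (highest 40.5%) when footprints were moved at random inside their peaks.

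Sites of general chromatin and promoter factors were the most concentrated in footprints. CTCF, the insulator protein, had odds ratios of 282 and 138 against control windows in replicates 1 and 2, NRF1 33.8 and 53.4, SP/KLF 9.56 and 9.02, CRE 9.01 and 7.29, and YY1 3.53 and 2.46. REST matched 89 and 105 footprints and 0 control windows, an odds ratio of at least 29.7 and at least 35.0 at a floor of 3 counts. Of the factor families known for T cell development, ETS had 1.84 and 2.06, TCF1/LEF1 1.46 and 1.39, and the E-box of E proteins 1.30 and 1.24. RUNX and GATA, also families with members in the T lineage list, were not more frequent in footprints than in these control windows. GATA (0.549 and 0.444), AP-1 (0.502 and 0.460) and CRX/OTX (0.692 and 0.690) were rarer in footprints than in the control windows. RUNX (0.960 and 0.925), NFY (0.944 and 0.841), IRF (1.30 and 0.807), NF-kB (0.789 and 0.933) and MEF2 (0.649 and 0.300) did not pass in both libraries, and HNF1 had 0 matches. These odds compare 253415 and 296691 pairs of windows, and 12 of 18 motifs passed by Fisher's exact test, which did not use the pairing. Footprints were richer in GC than control windows, at 59.2% against 53.5% and 62.1% against 55.1%. With control windows matched on GC, a choice made after seeing the data, GATA and CRX/OTX no longer passed, and RUNX passed at a mean odds ratio of 1.42. NFY (1.21 and 1.25) and IRF (2.96 and 2.19) then passed as more frequent in footprints, and NF-kB (0.507 and 0.669) as rarer. CTCF fell to 124 and 89.7, SP/KLF to 5.78 and 4.68 and the E-box to 1.11 and 1.12. TCF1/LEF1 rose to 2.01 and 2.32 and ETS to 2.07 and 2.34, and NRF1 stood at 217 and 30.2. The sizes also depended on the extension: without it CTCF stood at 607 and 639 and SP/KLF at a mean of 16.5. TCF1/LEF1 then stood at 1.23 and 1.12 and no longer passed (adjusted p = 0.224 and 0.43, Fisher's exact test). YY1 without extension stood at 3.31 and 1.74 and passed in replicate 1 alone. At footprints over 1000 bases from a TSS, NFY passed in the other direction, at 0.782 and 0.684. YY1 matched 3 and 2 of those footprints, against 0 and 2 control windows.

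**Figure D4:**
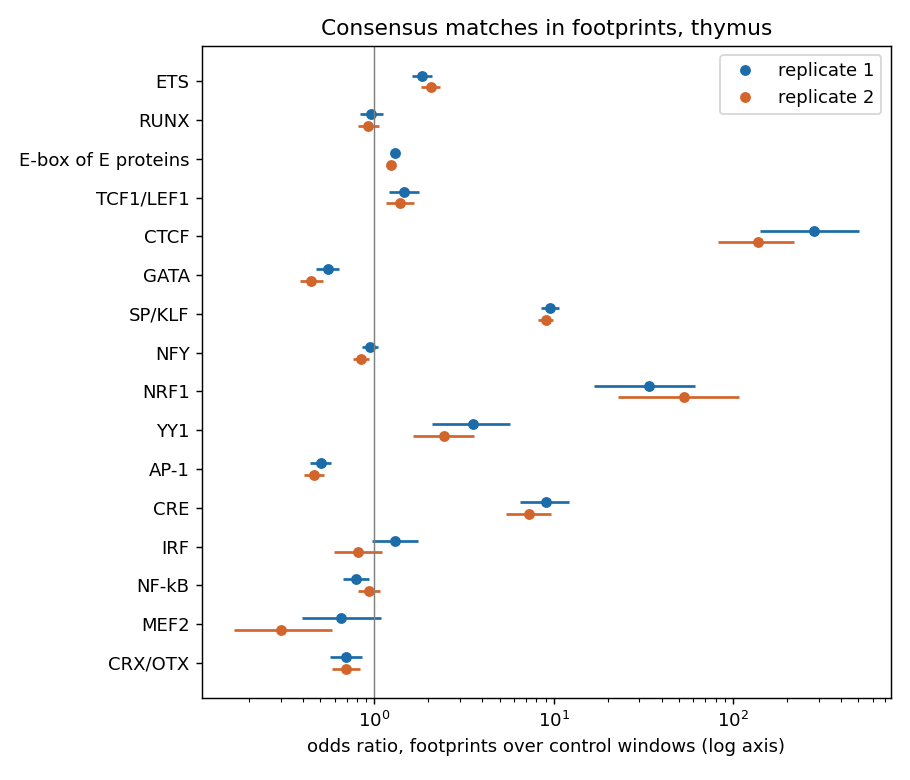
Odds ratio of a consensus match in footprints over control windows (x axis, log scale) for 16 motifs, 1 point per library with its 95% interval; REST and HNF1 are not drawn. CTCF lies farthest to the right at 282 and 138, and GATA, AP-1 and CRX/OTX lie left of 1 in both libraries.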

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

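The 5 gene lists called for promoter peaks and the 2 called for distal peaks kept their calls under every alternative run, and with each library alone (5 to 6 and 2 lists). Skeletal muscle was also called lower with the stricter list, within 500 bases of a TSS and in replicate 1 alone. With the stricter list, peaks per library averaged 85069, the promoter share was 38.7%, X over autosomes 0.365 and rho 0.944. Promoter peaks made up 24.2% within 500 bases and 28.7% at protein-coding TSSs. Reciprocal 50% overlap gave 61.0% shared peaks, 38.8% shared footprints and a rho of 0.950. By library, peaks ranged from 116560 to 142851, footprints from 348229 to 440424, promoter share from 31.6% to 34.5% and X over autosomes from 0.404 to 0.410. Of 12 motif calls, 10 remained without extension (TCF1/LEF1 and YY1 lost), 10 with a reordered consensus (AP-1 and CRX/OTX lost; AP-1 reads the same on both strands, so chance alone puts it below 1 there), 11 at distal footprints (YY1 lost, NFY gained as rarer) and 10 with GC-matched windows (GATA and CRX/OTX lost), the last chosen after seeing the data. RUNX turned from below 1 to 1.42 with GC-matched windows, and NFY to 1.23. Against a reordered consensus RUNX stood at 3.11 and NFY at 2.52. That setting compares words within footprints and uses no control windows, so it does not show more sites inside footprints than outside them. Among the other values, for single lists, motifs and genes, 327 kept their call, stayed without a call or, for genes, were not counted as moved. Values under a kept call could shift. All 43 that moved were peak numbers of named genes. With distal regions of 50000 bases 14 genes moved and 16 did not, and with the stricter list likewise 14 and 16. Without replicate 1, 5 moved and 25 did not, and without replicate 2, 10 and 20. Of lists and motifs, 10 came to pass the test, 6 no longer passed and 4 turned. Motifs without a finite odds ratio were left out, among them YY1 at distal footprints, so its lost call is not among the 6. The cause of these changes was not tested. Restricting to footprints above the median score was not run, since every score was equal. With unknown depth, a missing peak sets no limit, and lists raised 2-fold in distal peaks were mostly missed in simulation.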

Other observations

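Gene families outside the fixed lists, chosen after the data were seen, ranged from almost no open promoters to nearly all. Olfactory receptors had a promoter peak at 25 of 1134 genes in replicate 1 and 30 in replicate 2, and vomeronasal receptors at 2 of 330 in each. Keratin-associated proteins had 2 and 3 of 57. Ribosomal protein genes had 79 of 82 in each library, proteasome subunits 37 and 38 of 39, replication-dependent histones 59 of 67 in each, and genes named Zfp 320 and 321 of 365. Interleukins had 13 and 15 of 33 (adjusted p = 0.00166 and 0.0055, Fisher's exact test), interleukin receptors 30 and 31 of 41 (0.507 and 0.498), chemokine receptors 8 and 9 of 18 (0.0831 and 0.0898), and Hox genes 13 and 22 of 39 (4.08e-05 and 0.0898). The background for Hox genes was 66.9% and 69.6% of other genes, so Hox genes lay below it in both libraries and passed the test in replicate 1, and neither receptor family passed.

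Antigen receptor loci had peaks at many V segments of the T cell receptors and of Igh, and at almost none of Igk. V segments with a peak within 1000 bases of their start numbered 54 and 61 of 108 at Tcra, 12 and 16 of 22 at Tcrb, 5 and 4 of 7 at Tcrg and 4 and 4 of 5 at Tcrd. At Igh they numbered 70 and 73 of 113, whereas Igk had 1 of 100 in each library and Igl had 0 of 3. Igh and Igk differed in both libraries (p = 1.14e-24 and 2.55e-26, Fisher's exact test, chosen after seeing the data). T cell receptor V segments together exceeded immunoglobulin V segments with odds ratios of 2.29 and 2.86 (p = 0.00019 and 2.58e-06, Fisher's exact test). Against Igh alone the odds ratios were 0.688 and 0.817 (p = 0.162 and 0.516, Fisher's exact test), so a difference from Igh was not shown in either direction. These tests were also chosen after seeing the data. Neighbouring segments are not independent. The Igh D, J and C region on chromosome 12, 113254830 to 113525329, held 13 peaks in replicate 1 and 56 in replicate 2, or 0.481 and 2.07 per 10 kb. The Tcra J and C region held 20 and 18 (2.94 and 2.64 per 10 kb), the Tcrb D, J and C region 24 and 19 (15.8 and 12.5), and the Igk J and C region 0 in each.

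In the tests below, those of T cell share, of AP-1 and GATA separately, of reordered letters in windows and of the change on merging were chosen only after the result was seen, and the settings with merged peaks and GC-matched windows were added after the data were seen.

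The T cell lists had more distal peaks in replicate 2, with 1022 distinct peaks against 702. Counting a peak near several list genes for each gave 1060 against 717 (1.48-fold). All protein-coding genes rose 1.30-fold, and summed counts rose more for receptor gene recombination (2.29), dendritic cell (2.15), myeloid (1.77) and B cell lists (1.53). Such sums can rest on few loci. The neighbours Rag1 and Rag2 had 7 and 8 distal peaks in replicate 1 and 34 and 47 in replicate 2. By median log2 ratio per gene, myeloid genes (0.12) lay below the T cell lists (0.40 and 0.41). Receptor gene recombination (0.59), dendritic cell (0.49) and B cell genes (0.49) lay above them. Higher enrichment at every accessible gene is a candidate explanation, since both T cell lists lay within the range of random lists matched on strength (percentiles 78.3 and 85.3), although above their medians. For splitting of single domains, merging peaks under 500 bases apart moved the ratio relative to all genes from 1.14 (0.994 to 1.32 over resampled genes) to 1.23 (1.10 to 1.37). The lists' own ratio hardly moved (1.478 and 1.475), whereas that of all genes fell from 1.30 to 1.203. The merged relative ratio met the bound written beforehand against splitting, more than 10% above all genes. That bound was not met by more than the spread of the ratio, a condition that was not part of it. The merged relative ratio stayed above 1, which argues against splitting at this distance as the only reason at these lists. The change of 1.08-fold had an interval of 0.984 to 1.18 over 37 resampled loci, so splitting as a part, or over longer distances, stays open. A larger T lineage share also cannot be told apart, because the receptor signalling list stood at percentile 6.71 with all its peaks and 80.8 with distal peaks alone. The first written bound, a percentile under 50, was met and argued against this share; the need for distal peaks and an interval was added after 6.71 was seen.

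Peaks on chromosome Y do not look like male tissue: Ddx3y, Uty, Kdm5d and Eif2s3y had a promoter peak in 0 of 4 cases in either library, and their X partners Ddx3x, Kdm6a, Kdm5c and Eif2s3x in 4 of 4. Away from its promoter, Uty had 0 peaks in replicate 1 and 2 in replicate 2, inside the gene or within 25000 bases of it. Sequence shared with other chromosomes may account for part: 45.8% of Y peaks had over 50% of their 32-base words on X or an autosome, between the bounds set beforehand. That share averaged unlike regions, a split looked at only afterwards. From 90717601 to 90744820 of Y, only the strongest peak of each library (6.35 and 12.9) had over 50%. Elsewhere on Y most peaks had over 50%, so shared sequence is a candidate there. For most peaks of that block the count did not reach 50%. It finds only exact words of the mm10 sequence, so it cannot exclude copies that this sequence lacks or that differ in bases. Words repeated anywhere, Y included, made up over 50% of the sequence in 45 of 65 and 53 of 66 Y peaks, against 5 of 200 random peaks. No biological explanation was tested.

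GATA and AP-1 sites were rarer in footprints than outside them in the same peaks. With GC-matched windows AP-1 stayed at 0.671 and 0.590 (upper bounds 0.783 and 0.680), which argues against the GC content of whole windows as the only reason, whereas GATA rose to 0.923 and 0.872, and its intervals of 0.775 to 1.10 and 0.725 to 1.05 leave GC content open. Base composition of the consensus is a candidate explanation for both, since reorderings of the same letters, set against the same windows, covered the values of both: AP-1 stood at percentile 11 at most (12.5 with GC matching) of 200 reorderings and GATA at 44.7 (67.6) of 179. Some of the 200 for AP-1 were reverse complements of each other and matched the same sites. Fewer than 200 were therefore distinct, and the AP-1 percentiles are approximate. GATA lay close to the medians of its reorderings, at 0.55 against 0.57 and 0.44 against 0.46 in replicates 1 and 2. AP-1 lay below its own, at 0.50 against 0.71 and 0.46 against 0.61. With GC matching AP-1 stood at 0.67 against 0.91 and 0.59 against 0.86, so composition covers less of its value. Within footprints alone, AP-1 against its reordered consensus gave 0.820 and 0.933 and GATA 0.727 and 0.759, a comparison without sites outside footprints, in which chance alone puts AP-1 below 1 because its consensus reads the same on both strands. The value that chance gives was not computed, so these AP-1 values do not show that AP-1 is rare in footprints. Beforehand both motifs were to be judged together, and they parted on GC matching; no biological explanation was tested.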
